A study of Mus musculus with 12 samples.

How the data were processed

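RNA was measured in nuclei sorted from mouse hippocampus, in 12 libraries titled Basal, Early, Late and Reactivated, with 3 libraries per title. The mice carried a tamoxifen-dependent Cre recombinase driven by the Arc gene and a Cre-dependent yellow fluorescent reporter, so that neurons with active Arc around the time of the drug stayed marked. Per the labels, 4-hydroxytamoxifen was given 1 h before fear conditioning, with 24 h of darkness before it and 48 h after it. Tissue was taken 1.5 to 2 h after conditioning or on day 5, and part of the mice met the cue again before the later collection. Nuclei were fixed in 1% paraformaldehyde and sorted with antibodies to NeuN (a protein of neuronal nuclei), Arc and GFP. The labels give 10000 nuclei per condition, pools of 10 to 12 mice and 3 biological replicates, so a replicate is a pool of mice. The treatment field reads the same for all 12 libraries and gives day 0 as the collection day of each, so groups were taken from the titles alone. That Late and Reactivated are of the later collection is therefore read from their titles and the protocol, and no label states which sorting gate belongs to which title. The labels name a stranded total RNA kit with depletion of ribosomal cDNA and 15 PCR cycles in one place and SmartSeq2 in another.

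The processing notes of the authors name Bowtie2 2.0, Cufflinks 2.2, DESeq2 without a version and the mouse build mm9, without stating what each did. The tool that counted reads, its gene annotation and its strand setting are not given in the sources used here. The deposited table holds 1 count per gene symbol and library for 24015 rows, of which 2989 were 0 in all 12 libraries. The name of the table calls the values normalized, but the values showed no scaling. They were whole numbers with totals of 4838166 to 11120255 per library and 0 empty whole numbers between 1 and 30. Median-of-ratios size factors, which are near 1 in values already divided by them, began at 0.734 in the lowest library. The values were therefore treated as raw counts. In 27 rows the symbol had become a calendar date, and these rows held at most 0.158% of the counts of a library. A further property of the table is that 4 rows share their symbol with another row. Genes of the mitochondrial genome were not listed under the symbols looked up, and positions of genes are not given because the annotation at hand is of a later build. GC content came from that annotation, for 15461 of the 15668 genes tested (98.7%).

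Genes with a count of at least 10 in at least 3 of the 12 libraries were tested, 15668 in all. The test was the quasi-likelihood test of edgeR 4.0.16 with TMM scaling in R 4.3.3, with the 4 group means fitted to all 12 libraries together. All 6 pairs of groups were compared, and a test of any difference among the 4 groups was made in the same fit. P-values were two-sided and adjusted by Benjamini and Hochberg over all genes tested within a comparison, with a threshold of 0.05. Normalized counts are counts divided by the effective library size relative to the geometric mean over libraries. Levels are given as mean ± SD of normalized counts with n = 3 libraries per group, and log2 fold changes are given ± SE. A gene that "rose" or "fell" passed that threshold. A prior count of 2 was used for log2 CPM (counts scaled to a common library total). The median of the trended dispersion was 0.0394.

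The 31 gene lists, with 516 distinct genes, covered activity, synapse, metabolism, RNA handling, hippocampal subfields, other cell types and sex-linked genes. The table held 495 of these genes. The 28 lists with at least 4 tested genes were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation and with fry, and adjusted over the 28 lists within a comparison. For each list the number of members that passed was also counted with p-values adjusted over the list alone. Summed counts of the lists per library were compared between groups by exact two-sided permutation tests, where 3 against 3 libraries cannot give a p below 0.1, and adjusted over 120 tests. Correlations across genes are descriptive, because genes are not independent replicates.

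Genes to name were chosen by rule from those that passed, had a mean of at least 50 in the higher group and did not overlap between the 3 libraries of each group. The 10 largest changes in each direction were taken in the comparisons with Basal and of Reactivated with Late, and 5 in each direction in the other comparisons. Unnamed gene models, genes with snoRNA, scaRNA or microRNA symbols and symbols turned into dates were not named, so larger changes among these are not listed. Arc, Fos, Npas4, Egr1, Nr4a1 and Bdnf were added in every comparison, with up to 4 members of each list by p-value. Some genes that this rule named are not reported here. The comparisons, lists, naming rule, filter and 16 alternative settings were chosen before the data were examined. The design had fixed limma on log2 values for the case of normalized values. It was replaced by edgeR once the values proved to be counts, and limma on the values as deposited was kept as an alternative. That setting and the other 7 of 8 added alternatives were chosen after seeing the data. They included the share of Rn45s (the 45S precursor of ribosomal RNA) as a covariate and a correction for GC content.

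Alternatives also covered DESeq2 1.42.0, other scalings, filters, pseudocounts and library weights, the replicate number as a block, and fits without each of the 12 libraries in turn. A fit that left a group with 2 libraries kept the spread shared by all groups. Libraries of Basal and Early with the same number correlated across genes at 0.331, 0.143 and 0.484, where the highest with another number was 0.168, 0.223 and -0.223. Numbers 1 and 3 thus went together and number 2 did not, and the blocked values are given beside that comparison. For Reactivated and Late the values were 0.059, 0.066 and 0.166 against -0.013, 0.033 and -0.061, and in the other comparisons at least 2 of 3 same-number correlations were no higher than the highest with another number. Simulated data tested the method, with genes changed in Early. They were built from the Basal means and from the library sizes and fitted spread of all 12 libraries. The edgeR test recovered 49 of 100 genes changed 2-fold and 81 of 100 changed 4-fold, with 9 unchanged genes called among 15668 genes, and 0 of 28 random lists passed. DESeq2 recovered 63 and 83 with 31 unchanged genes called. Each gene was drawn independently, without variation that libraries share across genes. The counts of false calls and of random lists passed can therefore understate those in the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps. PCR reads without molecular identifiers are not independent molecules, so counting error is only a lower bound on the error of a single library.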

Results

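Nuclear RNA was measured in 12 libraries of sorted mouse hippocampal nuclei, 3 each of the groups titled Basal, Early, Late and Reactivated. Total counts were 4838166, 5693302 and 10255713 in Basal, 6378949, 9635754 and 9653364 in Early, 10794998, 9705505 and 11120255 in Late, and 7356465, 10327059 and 9958793 in Reactivated. Between 16965 and 18643 genes had a count above 0 in a library. Replicates were correlated across genes on log2 of normalized counts plus 1. The r was 0.954 to 0.974 in Basal, 0.967 to 0.985 in Early, 0.979 to 0.981 in Late and 0.917 to 0.955 in Reactivated. Of the 15668 genes tested, 9180 (58.6%) differed among the 4 groups. The first principal component held 49.0% of the variance and the next 17.9%.

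Rn45s, the precursor of ribosomal RNA, took 7.36% ± 4.19 of the counts in Basal, 8.51% ± 3.83 in Early, 33.4% ± 4.76 in Late and 22.4% ± 4.69 in Reactivated (SD, n = 3 each). Every Late and Reactivated library lay above every Basal and Early library (exact two-sided permutation p = 0.1 for each of these pairs of groups, the smallest that 3 against 3 libraries allow). Basal 3 and Early 3 had the highest shares of their groups, 12.2% and 12.9%. The share therefore goes with the groups, and no label names a library batch. Lars2 took 4.08% ± 0.536 of the counts in Reactivated and 0.450% ± 0.305 in Basal. It is the symbol of the mitochondrial leucyl-tRNA synthetase, but was placed with Rn45s on the list of structural noncoding RNAs. Whether its reads come from the messenger RNA of the synthetase was not tested. Malat1, an abundant nuclear long noncoding RNA, took 7.16% ± 0.907 in Basal, 7.91% ± 0.270 in Early, 4.10% ± 0.599 in Late and 3.80% ± 0.725 in Reactivated.

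**Figure D1:**
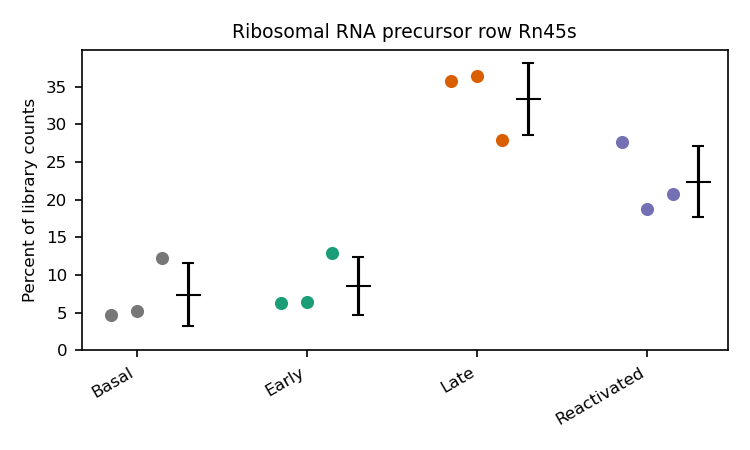
Percent of the counts of each library that fell on Rn45s, by group, with 1 point per library and a dash with bars for the mean ± SD (n = 3). The Late libraries sit between 27.9% and 36.5% and the Reactivated libraries between 18.8% and 27.7%, above all Basal and Early libraries.

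Early against Basal asks how nuclei collected in the first hours after conditioning differ from the comparison nuclei. Markers of dentate gyrus granule cells were lower in Early. Of 14 tested, 13 fell (13 adjusted over the list alone), with a median log2 fold change of -2.04 (adjusted p = 1.35e-31, and adjusted p = 0.0185 with an estimated correlation). Prox1, a transcription factor of granule cells, fell 5.63-fold (log2 fold change -2.49 ± 0.33, adjusted p = 0.000386). Dock10, a guanine nucleotide exchange factor, fell 5.70-fold, Trpc6, a cation channel, 5.25-fold and Pdzd2 2.79-fold. The summed normalized count of the list was 12504 ± 2565 in Basal and 2854 ± 260 in Early (n = 3 each, exact permutation p = 0.1, adjusted p = 0.162).

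Markers of CA1 pyramidal neurons were higher in Early, with 8 of 10 up (9 adjusted over the list alone) and a median of 1.21 (adjusted p = 7.32e-14, and adjusted p = 0.00335 with an estimated correlation). Gpr161, an orphan receptor, rose 4.24-fold (log2 fold change 2.08 ± 0.20, adjusted p = 3.79e-05), Wfs1 2.81-fold, Lefty1 4.77-fold and Mpped1 2.05-fold. Of 11 markers of CA3 and CA2 pyramidal neurons, 4 rose (6 adjusted over the list alone), with a median of 0.72 (adjusted p = 3.33e-06, and adjusted p = 0.0586 with an estimated correlation). Iyd rose 7.56-fold, Amigo2 3.37-fold, Hs3st4 2.82-fold and Grik4, a kainate receptor subunit, 2.12-fold. Of 19 interneuron markers, 3 rose and 5 fell (5 and 6 adjusted over the list alone), with a median of -0.33 (adjusted p = 0.0395, and adjusted p = 0.713 with an estimated correlation). Vip, a neuropeptide of one interneuron class, fell 11.8-fold, Erbb4 2.75-fold and Adarb2 1.86-fold, and Cnr1, the cannabinoid receptor, rose 2.72-fold. The interneuron call ended with the replicate number as a block (median -0.34) and without Basal 1 (-0.25), Basal 3 (-0.26), Early 3 (-0.05) or Reactivated 2 (-0.33). It also ended in limma with pseudocounts of 1 (-0.39), 0.5 (-0.39) or 5 (-0.38) and with the Rn45s share of each library as a covariate (-0.31), a setting added after seeing the data, and the median turned to 0.03 without Basal 3 and Early 3 together.

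**Figure D2:**
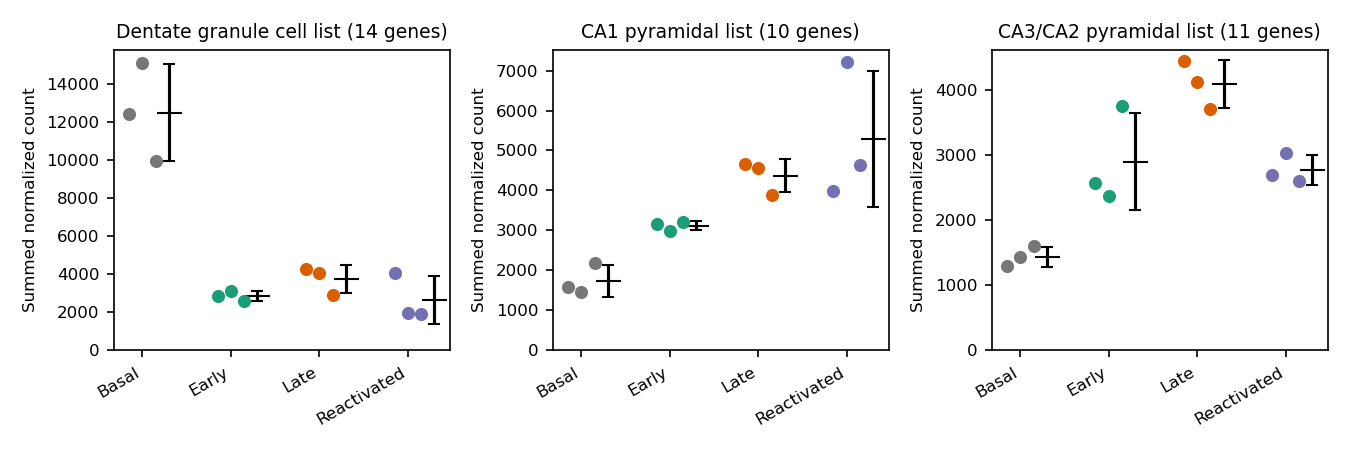
Summed normalized counts of the marker lists of dentate granule cells (14 genes), CA1 pyramidal neurons (10 genes) and CA3 and CA2 pyramidal neurons (11 genes), with 1 point per library and a dash with bars for the mean ± SD (n = 3). The granule cell sum is 12504 in Basal and 2854 in Early, and the CA1 sum is 1739 in Basal and 3114 in Early, on means.

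Activity-regulated genes were higher in Early as a group. Of 21 immediate early genes, 6 rose and 2 fell (9 and 2 adjusted over the list alone), with a median of 0.66 (adjusted p = 6.41e-06, and adjusted p = 0.106 with an estimated correlation). Arc, whose protein was used to sort the nuclei, rose 2.97-fold, from 145 ± 40.7 to 435 ± 110 normalized counts (log2 fold change 1.57 ± 0.23, adjusted p = 0.000795). Nr4a1 rose 2.59-fold, Npas4 2.37-fold and Egr1 2.24-fold, all transcription factors induced by activity. Fos (1.20 ± 0.51, adjusted p = 0.226, though it passed with array weights at 1.50) and Bdnf, a neurotrophin (-0.04 ± 0.25, adjusted p = 0.974), did not pass. Btg2 fell by 1.84 ± 0.30 and Jun by 0.78 ± 0.16 on the log2 scale. Of 20 late response genes, 6 rose (6 up and 1 down adjusted over the list alone), with a mean of 0.20 and a median of 0.04, which was -0.04 when libraries were scaled to the same total (adjusted p = 0.0105, and adjusted p = 0.145 with an estimated correlation). Ptgs2, a cyclooxygenase, rose 2.57-fold, Vgf 2.10-fold, Plk2 1.90-fold and Homer1 1.69-fold. This list call ended without Basal 3 (median 0.07) or Early 1 (0.03).

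Of 21 presynaptic genes, 6 rose (11 adjusted over the list alone), with a median of 0.38 (adjusted p = 1.67e-08, and adjusted p = 0.145 with an estimated correlation). Sv2b, a synaptic vesicle protein, rose 4.42-fold, Cplx1 2.18-fold, Snap25 1.76-fold and Slc17a7, a vesicular glutamate transporter, 1.56-fold. Of 27 ion channel genes, 4 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.17 (adjusted p = 0.0238, and adjusted p = 0.145 with an estimated correlation). The potassium channel gene Kcnq5 rose 3.66-fold, and the sodium channel gene Scn3a fell 1.75-fold. The channel list call ended without Basal 3 (median -0.0040), Early 1 (0.12) or Basal 3 and Early 3 together (0.10), and in limma with each of 3 pseudocounts (0.17). Of 12 heat shock genes, 2 rose, Hsp90ab1 1.68-fold and Hsp90aa1 1.57-fold (4 adjusted over the list alone, median 0.49, adjusted p = 0.00170, and adjusted p = 0.145 with an estimated correlation). Of 9 nuclear long noncoding RNAs, 3 rose, Snhg11 1.73-fold, Meg3 1.59-fold and Rian 1.56-fold (5 up and 1 down adjusted over the list alone, median 0.43, adjusted p = 0.00715, and adjusted p = 0.305 with an estimated correlation).

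Of 9 neurogenesis genes, 2 fell, the proliferation marker Mki67 2.76-fold and Calb2 3.47-fold (3 adjusted over the list alone, median -0.49, adjusted p = 0.000860, and adjusted p = 0.145 with an estimated correlation). Among 31 oxidative phosphorylation genes none passed alone (0 adjusted over the list alone), with a median of 0.30 (adjusted p = 0.00715, and adjusted p = 0.307 with an estimated correlation). That call ended without Early 1 (median 0.21). Among 38 chromatin regulators Stag1, a cohesin subunit, fell 1.38-fold (0 adjusted over the list alone), with a median of -0.10, or 0.17 on the values as deposited (adjusted p = 0.0325, and adjusted p = 0.549 with an estimated correlation). The chromatin call ended without Basal 3 (median -0.08), Early 1 (-0.08) or Early 2 (-0.11). Markers of blood vessels summed to 383 ± 372 normalized counts in Basal and 132 ± 18.8 in Early, with 812 in Basal 1. None of the 10 tested fell alone (5 adjusted over the list alone), with a median of -1.72 (adjusted p = 0.0165, and adjusted p = 0.490 with an estimated correlation). Without Basal 1 that median was -0.46 and with the Rn45s share as a covariate -1.29, and the call ended in both.

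Unnamed gene models and genes with snoRNA, scaRNA or microRNA symbols were left out of the genes named for size in every comparison, while 2 snoRNA genes with other symbols, AF357399 and AF357359, were kept. Among the other genes that met the naming rule, the largest rises in Early were in neighbouring kallikrein-related protease genes, Klk10 (25.5-fold, 101 ± 19.1 against 3.53 ± 1.93 normalized counts, n = 3 each), Klk8 (14.2-fold) and Klk9 (log2 fold change 3.81 ± 0.34), whose related sequences leave the assignment of reads uncertain. Slc9a2, a sodium and proton exchanger, rose 8.27-fold, Pvrl3, an adhesion molecule, 6.50-fold and Skap2 5.81-fold. Zap70, a tyrosine kinase, rose 5.08-fold, Dusp5, a phosphatase of ERK, 5.02-fold and Lrp2, an endocytic receptor, 4.82-fold. Pvrl3 is the older symbol of the CA3 and CA2 marker Nectin3, which was looked up under the newer symbol and is not in the list counts. The largest falls among them besides Vip were in Card14 (11.8-fold, 85.8 ± 38.8 to 7.05 ± 1.63), Plk5 (8.78-fold), C1ql2, a synaptic organizer of granule cells (7.24-fold), and Baiap3 (6.46-fold). Postn, an extracellular matrix protein, fell 5.82-fold, Ccdc33 5.71-fold, Ahnak 5.68-fold and Glis3, a zinc finger factor, 5.67-fold. Without Basal 3 the log2 fold change of Klk10 moved from 4.67 to 5.32 and that of Zap70 from 2.34 to 3.32. The call of Postn ended without Basal 2 (-2.40), without Basal 3 and Early 3 together (-2.47) and in limma with a pseudocount of 1 (-2.47) or 0.5 (-2.51). That of Ccdc33 ended without Basal 2 (-2.30), Early 1 (-2.45) or Early 2 (-2.54) and with a pseudocount of 0.5 (-2.45). The call of Ahnak ended without Basal 1 (-1.01), Early 1 (-2.67), Early 2 (-2.59) or Early 3 (-2.27), and with pseudocounts of 1 (-1.92), 0.5 (-1.93) or 5 (-1.85), quantile normalization (-2.03), a fit of the 2 groups alone (-2.51) or the Rn45s covariate (-2.08).

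In all, 527 genes rose and 417 fell in Early against Basal (944 of 15668), 271 and 231 of them at least 2-fold, and the 3 libraries of the groups did not overlap for 23.4% of all genes, where chance gives 10%. With the replicate number as a block 928 genes passed, of which 866 had passed without it. The count was 596 without Basal 1, 487 without Basal 2, 549 without Early 1 and 614 without Early 2. With libraries scaled to the same total the split was 341 higher and 446 lower, and on the values as deposited it was 338 higher and 72 lower.

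Late against Basal asks how the nuclei titled Late, read from the protocol as those of the later collection, differ from the comparison nuclei. Granule cell markers were lower, with 12 of 14 down (12 adjusted over the list alone) and a median of -2.82 (adjusted p = 2.95e-07, and adjusted p = 0.389 with an estimated correlation). Prox1 fell 13.7-fold, from 1636 ± 196 to 120 ± 9.52 normalized counts (log2 fold change -3.77 ± 0.36, adjusted p = 1.95e-06), Dsp, a desmosome protein, 13.6-fold, Dock10 10.9-fold and Trpc6 6.32-fold. CA1 markers were higher, with 9 of 10 up (9 adjusted over the list alone) and a median of 1.78 (adjusted p = 2.24e-05, and adjusted p = 0.0803 with an estimated correlation). Gpr161 rose 5.37-fold, Man1a 5.07-fold and Wfs1 3.13-fold. Of 8 markers of subiculum and cortex, 6 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 2.10 (adjusted p = 0.0139, and adjusted p = 0.389 with an estimated correlation). The transcription factor genes Rorb, Foxp2 and Bcl11b rose 9.64-fold, 6.72-fold and 6.16-fold, and Fn1, fibronectin, 4.25-fold. Of 19 interneuron markers, 1 rose and 9 fell (1 and 9 adjusted over the list alone), with a median of -0.60 (adjusted p = 0.0156, and adjusted p = 0.757 with an estimated correlation). Vip fell 15.9-fold, Erbb4 3.53-fold and Adarb2 2.31-fold.

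Of 21 immediate early genes, 13 rose and 2 fell in Late (13 and 2 adjusted over the list alone), with a median of 1.02 (adjusted p = 0.0242, and adjusted p = 0.553 with an estimated correlation). Fosb rose 6.15-fold, Arc, used in the sort, 4.05-fold to 593 ± 48.0 normalized counts, Nr4a1 2.69-fold and Npas4 2.60-fold, while Btg2 fell 5.45-fold. Egr1 rose 1.50-fold (log2 fold change 0.58 ± 0.20, adjusted p = 0.0229) and Fos 2.73-fold (1.45 ± 0.51, adjusted p = 0.0292). The Egr1 call ended without Basal 2 (0.55), Basal 3 (0.49) or Late 3 (0.49), with upper quartile scaling (0.36), on the values as deposited (0.40) and with GC correction (0.21, or 0.23 with the block as well). With libraries scaled to the same total Egr1 was at -0.26, and with the Rn45s covariate and the block it stayed called at 1.54. The Fos call ended without Basal 1 (1.30), Basal 2 (1.30) or Late 1 (1.25), with upper quartile scaling (1.23), with the same total (0.64) and on the values as deposited (1.27). Bdnf rose 2.33-fold, to 710 ± 183. With the same total the calls of Bdnf (0.35) and Npas4 (0.55) ended too. Of 21 presynaptic genes, 17 rose (17 adjusted over the list alone), with a median of 0.96 (adjusted p = 1.14e-05, and adjusted p = 0.389 with an estimated correlation). Cplx2 rose 4.08-fold and Slc17a7 2.36-fold. Of 4 Y-linked genes, 3 fell (4 adjusted over the list alone), Uty 2.76-fold, Eif2s3y 2.43-fold and Kdm5d 2.39-fold (median -1.27, adjusted p = 0.0139, and adjusted p = 0.250 with an estimated correlation).

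**Figure D3:**
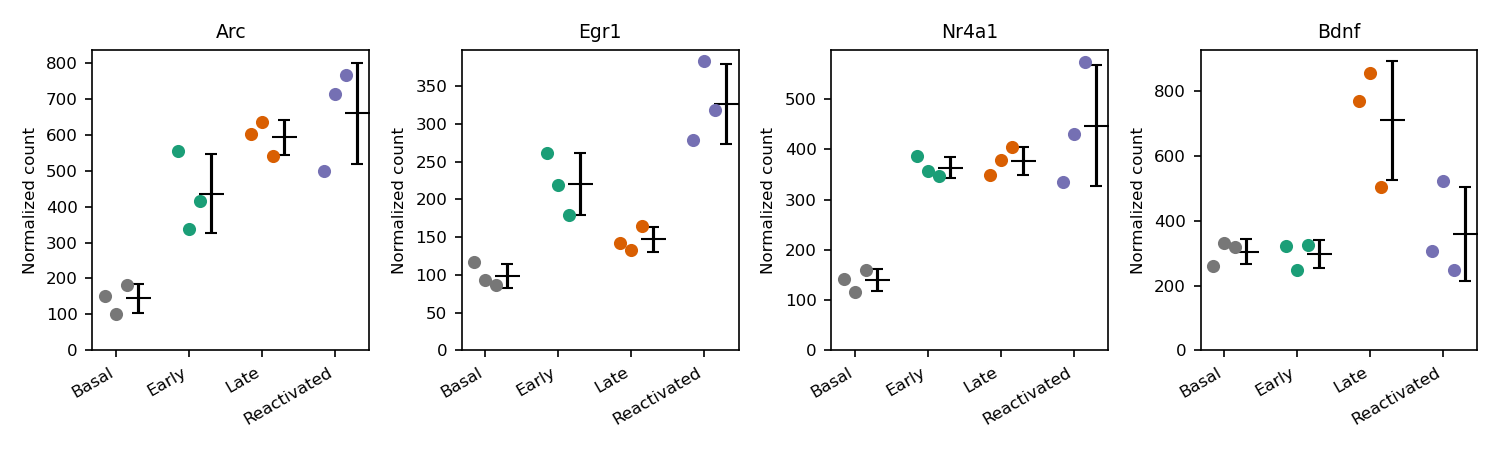
Normalized counts of Arc, Egr1, Nr4a1 and Bdnf by group, with 1 point per library and a dash with bars for the mean ± SD (n = 3). Arc is 145 in Basal and 435, 593 and 660 in Early, Late and Reactivated, and Bdnf is 710 in Late against 304, 298 and 359 in Basal, Early and Reactivated, on means.

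Markers of microglia and of oligodendrocytes split within their lists in Late. Of the 9 microglia genes tested, 3 rose and 4 fell, Itgam up 13.4-fold and Cx3cr1 11.6-fold, and P2ry12 and Csf1r down 3.93-fold and 2.77-fold. Of 12 oligodendrocyte genes, 3 rose and 5 fell, among them Mobp up 2.03-fold and Mog and Ermn down 4.70-fold and 2.79-fold, all of myelin. Neither list passed as a whole (adjusted p = 0.732 and adjusted p = 0.456). Summed counts of the microglia list were 820 ± 46.4 in Basal and 7755 ± 2048 in Late (n = 3 each, exact permutation p = 0.1, adjusted p = 0.162), and Itgam at 3820 and Cx3cr1 at 3841 made up nearly all of the Late sum. The oligodendrocyte sum was 3160 ± 422 in Basal and 8364 ± 2608 in Late (exact permutation p = 0.1, adjusted p = 0.162). Sums of the astrocyte and oligodendrocyte precursor lists were lower in Late. They were 2874 ± 229 against 6385 ± 1413 in Basal and 232 ± 15.1 against 503 ± 110 (exact permutation p = 0.1, adjusted p = 0.162 for each).

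With those symbols aside, the largest rises in Late among genes that met the naming rule began with Mmrn2. Mmrn2, a matrix protein of blood vessels, rose 112-fold to 9235 ± 4459 normalized counts (log2 fold change 6.80 ± 0.47), Cdx2, an intestinal homeobox factor, 87.2-fold, Nrp 66.4-fold and Dlx3, another homeobox factor, 47.2-fold. Adh6-ps1 rose 41.0-fold, Suclg2, a subunit of succinyl-CoA ligase, 39.6-fold and Srd5a3, of the steroid reductase family, 34.8-fold. Slc25a34 rose 28.9-fold, and Foxa3, a forkhead factor, rose by a log2 fold change of 4.81 ± 0.42. Abca15 was at 55.1 ± 17.9 in Late and 0.853 ± 0.755 in Basal, where its 3 libraries held 3 counts, and the folds of Cdx2 and Dlx3 rest on 7 and 4 counts in Basal. The largest falls, with the same genes left out, were in Lrrc17 (49.9-fold, 138 ± 3.02 to 2.91 ± 3.20), Glis3 (21.5-fold), Slc15a2, a peptide transporter (17.6-fold), Card14 (17.2-fold), Vip and Psg28 (15.5-fold). Slfn8 fell 15.1-fold, Spsb1 14.7-fold and Gsta3, a glutathione transferase, 14.4-fold. Psg28 belongs to a family of similar copies, so its reads are uncertain. Without Late 2 the log2 fold change of Lrrc17 moved from -5.64 to -6.89.

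In all, 3981 genes rose and 3706 fell in Late against Basal (7687 of 15668), 2277 and 2118 at least 2-fold, with no overlap for 62.5% of all genes, where chance gives 10%. With the Rn45s share as a covariate 821 genes passed. The median SE grew 2.06 times, so a call that ended with it does not show that the change went away. The calls of Abca15 (log2 fold change 5.66 to 2.01), Dlx3 (5.56 to 4.85), Slc25a34 (4.85 to 5.10), Foxa3 (4.81 to 2.85), Slfn8 (-3.92 to -1.0005), Spsb1 (-3.88 to -4.58), Arc (2.02 to 1.80), Fos (1.45 to 1.37), Npas4 (1.38 to 1.43) and Bdnf (1.22 to 0.81) ended, and with the block as well those of Cdx2 (5.78), Card14 (-3.70) and Slc15a2 (-2.58) also ended, as did those of the interneuron list (median -0.56) and the Y-linked list (-0.79). Correction for GC content ended the calls of the immediate early list (median 0.62) and the Y-linked list (-0.67). With libraries scaled to the same total the split was 1401 higher and 9069 lower, and the median over all genes was -0.87, so directions are relative to the TMM scaling; upper quartile scaling gave 3016 and 5114 with a median of -0.26.

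Reactivated against Basal asks how the nuclei titled Reactivated, read from the protocol as linked to the second meeting with the cue, differ from the comparison nuclei. Granule cell markers were lower, with 13 of 14 down (14 adjusted over the list alone) and a median of -2.46 (adjusted p = 2.39e-12, and adjusted p = 0.0874 with an estimated correlation). Dock10 fell 8.06-fold, Prox1 6.59-fold, Maml2 5.80-fold and Trpc6 5.25-fold. All 10 CA1 markers rose (10 adjusted over the list alone), with a median of 1.78 (adjusted p = 3.03e-10, and adjusted p = 0.0164 with an estimated correlation). Pou3f1, a transcription factor, rose 6.68-fold, Gpr161 6.44-fold, Fibcd1 4.11-fold and Wfs1 3.51-fold. Of 11 CA3 and CA2 markers, 7 rose (7 up and 1 down adjusted over the list alone), with a median of 0.72 (adjusted p = 0.0107, and adjusted p = 0.269 with an estimated correlation). Hs3st4 rose 3.76-fold, Iyd 3.16-fold, Rgs14 2.78-fold and Bok 2.00-fold. Of 8 markers of subiculum and cortex, 6 rose and 1 fell (6 and 1 adjusted over the list alone), with a median of 0.92 (adjusted p = 0.0414, and adjusted p = 0.335 with an estimated correlation). Fn1 rose 7.13-fold, Rorb 6.47-fold and Nts, neurotensin, 6.15-fold. This call ended without Reactivated 2 (median 0.83), without Basal 3 and Early 3 together (1.19), with a stricter filter of 50 counts in at least 3 libraries (0.77), in limma with pseudocounts of 1 (0.95), 0.5 (0.95) or 5 (0.92) and with the Rn45s covariate and the block (0.46).

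Of 21 immediate early genes, 14 rose and 1 fell in Reactivated (15 and 1 adjusted over the list alone), with a median of 1.47 (adjusted p = 1.27e-07, and adjusted p = 0.0783 with an estimated correlation). Arc rose 4.52-fold to 660 ± 141 normalized counts (log2 fold change 2.18 ± 0.23, adjusted p = 3.33e-05), Egr1 3.33-fold, Nr4a1 3.20-fold, Fosl2 3.63-fold and Npas4 2.71-fold. Fos rose 4.10-fold (2.03 ± 0.50, or 1.42 without Reactivated 2), and Bdnf (0.24 ± 0.25, adjusted p = 0.477) did not pass. Of 21 presynaptic genes, 18 rose (18 adjusted over the list alone), with a median of 0.77 (adjusted p = 2.36e-11, and adjusted p = 0.0874 with an estimated correlation). Cplx1 rose 5.67-fold, Sv2b 4.12-fold, Slc17a7 2.56-fold and Snap25 2.21-fold. Of 44 ribosomal protein genes, 26 rose and 1 fell (28 and 1 adjusted over the list alone), with a median of 0.71 (adjusted p = 2.00e-07, and adjusted p = 0.329 with an estimated correlation). Rps15 rose 3.88-fold, Rplp1 3.46-fold, Rpl19 3.30-fold and Rpl38 3.05-fold.

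Of 31 oxidative phosphorylation genes, 11 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.40, or -0.06 with libraries scaled to the same total (adjusted p = 0.0296, and adjusted p = 0.349 with an estimated correlation). Ndufa2 of complex I rose 2.79-fold, Atp5g3 of the ATP synthase 2.27-fold and Cox4i1 of complex IV 1.99-fold. This call ended with that scaling, with the stricter filter (median 0.36), and without Basal 3 (0.62), Reactivated 3 (0.38) or Basal 3 and Early 3 together (0.61). Of 12 heat shock genes, 5 rose (6 adjusted over the list alone), among them Hsp90ab1 2.86-fold, Hsp90aa1 2.09-fold and Hspa1b, which has a near-identical copy, 5.09-fold (median 0.64, or 0.45 with the stricter filter, where the call ended, adjusted p = 0.0115, and adjusted p = 0.329 with an estimated correlation). Of 7 genes tested in the structural noncoding RNA list, which also holds Rn45s and Lars2, 5 rose (5 adjusted over the list alone), among them Rnu11, a spliceosomal RNA, 5.32-fold, Rpph1 4.69-fold and Rmrp 3.60-fold (median 2.06, adjusted p = 0.00634, and adjusted p = 0.335 with an estimated correlation). All 4 Y-linked genes fell (4 adjusted over the list alone), Kdm5d 2.45-fold, Uty 2.08-fold, Eif2s3y 1.84-fold and Ddx3y 1.44-fold (median -0.97, adjusted p = 0.00272, and adjusted p = 0.0783 with an estimated correlation).

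Among the largest rises of genes that met the naming rule, unnamed models and snoRNA, scaRNA or microRNA symbols aside, Papl rose 12.4-fold, Tmem38b, a channel of the endoplasmic reticulum, 12.3-fold and Lars2 12.3-fold, from 31159 ± 23878 to 383325 ± 75267 normalized counts. Klk8 rose 11.5-fold, Klk14 10.5-fold, Inhbb, an activin subunit, 9.72-fold and Relb, of the NF-kappaB family, 9.61-fold. AF357399 rose 9.53-fold, Adamts7, a metalloprotease, 9.43-fold and Basp1, a protein of growing axons, 9.37-fold. The largest falls, with the same genes left out, were in Card14 (27.5-fold, with 9 counts in the Reactivated libraries together), Tmem45b (15.4-fold), Fcrl6 (14.6-fold) and Cenpp, a centromere protein (11.5-fold). Nr1h5 fell 10.3-fold, Vip 9.95-fold, Lct, lactase, 9.48-fold, Ccdc33 9.36-fold, Phxr4 8.57-fold and Plxna4os1 8.56-fold. Without Basal 3 the log2 fold changes of Papl (3.63 to 5.63), Klk14 (3.39 to 4.49), Relb (3.26 to 4.17), Lars2 (3.62 to 4.44), Adamts7 (3.24 to 3.91) and AF357399 (3.25 to 3.90) moved. Without Reactivated 1 those of Klk14 (2.58), AF357399 (2.44) and Ccdc33 (-3.23 to -4.07) moved. Without Reactivated 3 those of Tmem45b (-3.94 to -5.00), Cenpp (-3.52 to -4.31) and Plxna4os1 (-3.10 to -3.73) moved, and Tmem45b was at -3.29 without Reactivated 2.

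In all, 3223 genes rose and 2946 fell in Reactivated against Basal (6169 of 15668), 1514 and 1443 at least 2-fold, with no overlap for 45.8% of all genes, where chance gives 10%. With the Rn45s share as a covariate 776 genes passed. The calls of Papl (log2 fold change 2.89 with it), Tmem38b (2.13), Lars2 (1.53), Klk14 (0.52), Relb (2.38), AF357399 (1.82), Adamts7 (0.86), Tmem45b (-2.73), Nr1h5 (-1.32), Ccdc33 (-3.24), Plxna4os1 (-2.05) and Fos (1.98) ended, and with the block as well those of Cenpp (-2.26) and Fcrl6 (-3.25) also ended, as did that of the structural RNA list (median 0.17), and the Y-linked call ended with GC correction (-0.41). With libraries scaled to the same total the split was 1237 higher and 5833 lower, with a median over all genes of -0.46.

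The 3 comparisons share the same Basal libraries. Early and Late had 410 genes higher and 316 lower than Basal in both and 21 in opposite directions, where independent calls would give 134 and 98.6. Early and Reactivated shared 450 higher and 320 lower (108 and 78.4 if independent), with 3 opposite. Late and Reactivated shared 2308 higher and 2079 lower (819 and 697 if independent), with 131 opposite. The covariance of log2 fold changes across genes was 0.279, 0.267 and 0.727 for these pairs. It was 0.0690, 0.0685 and 0.0686 in 10 simulations of unchanged groups, which gave 0 genes called in both. The simulations drew all 12 libraries, Basal included, independently from the Basal means and the fitted spread. They lack variation that libraries share across genes, as Basal 3 and Early 3 do, so they can understate what shared controls give. The correlation was 0.430, 0.533 and 0.652 against 0.504, 0.508 and 0.494 in the simulations, and 65.1%, 68.2% and 78.4% of genes had the same sign against 66.5%, 66.7% and 66.7%, so on these measures Early and Late lay below the simulations. The 3 Basal libraries cannot be split into parts of at least 2, so part of the sharing that comes from the controls is not removed.

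Late against Early compares the titles read as the later and the first collection. Of 8 markers of subiculum and cortex, 5 rose in Late (5 adjusted over the list alone), with a median of 0.92 (adjusted p = 0.0206, and adjusted p = 0.683 with an estimated correlation). Foxp2 rose 8.20-fold (log2 fold change 3.04 ± 0.28, adjusted p = 1.84e-06), Bcl11b 7.03-fold, Rorb 6.15-fold and Cux2 2.14-fold. That call ended without Early 3 (median 0.92) and in limma with pseudocounts of 1 (0.93), 0.5 (0.93) or 5 (0.92). Of 9 neurogenesis genes, 6 rose (6 up and 1 down adjusted over the list alone), the transcription factor genes Eomes 16.5-fold, Neurod1 3.34-fold and Sox11 2.34-fold among them, and Draxin 4.15-fold (median 1.35, adjusted p = 0.0155, and adjusted p = 0.683 with an estimated correlation). Of 31 oxidative phosphorylation genes, 1 rose and 15 fell (1 and 15 adjusted over the list alone), with a median of -0.52 (adjusted p = 0.0203, and adjusted p = 0.683 with an estimated correlation). Cox6c fell 3.45-fold, Cycs, cytochrome c, 1.93-fold and Atp5b 1.79-fold. Of 4 Y-linked genes, 3 fell (3 adjusted over the list alone), Uty 2.70-fold, Eif2s3y 2.54-fold and Kdm5d 2.02-fold (median -1.18, adjusted p = 0.0206, and adjusted p = 0.538 with an estimated correlation).

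Bdnf rose 2.39-fold in Late against Early (log2 fold change 1.25 ± 0.25, adjusted p = 0.00131), and Egr1 fell 1.49-fold (-0.58 ± 0.19, adjusted p = 0.0223). Arc (0.45 ± 0.22, adjusted p = 0.117), Fos (0.25 ± 0.47), Npas4 (0.13 ± 0.18) and Nr4a1 (0.05 ± 0.18) did not pass. The Egr1 call ended without Early 1 (-0.44), Early 2 (-0.58), Late 1 (-0.55) or Late 2 (-0.52), and Arc passed without Early 1 (0.66) and with array weights (0.62). The Bdnf call ended with libraries scaled to the same total (0.48) and on the values as deposited (0.80). Npas4 (-0.63) and Nr4a1 (-0.70) passed as lower with the same total. Mmrn2 rose 86.8-fold, Nrp 44.1-fold and Adh6-ps1 36.7-fold. Cdx2 was at 211 ± 47.4 normalized counts in Late and 0.905 ± 0.844 in Early (3 counts in the 3 Early libraries), and Abca15 at 55.1 ± 17.9 and 0.348 ± 0.603 (1 count). Lrrc17 fell 102-fold, from 284 ± 46.7 to 2.91 ± 3.20 (log2 fold change -6.68, or -7.92 without Late 2). Slfn8 fell 19.5-fold, Gsta3 17.8-fold, Psg28 17.3-fold and Smn1, the survival motor neuron gene, 11.2-fold.

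In all, 3441 genes rose and 3187 fell in Late against Early (6628 of 15668), 1856 and 1618 at least 2-fold, with no overlap for 59.9% of all genes, where chance gives 10%. With the Rn45s share as a covariate 533 genes passed, and the calls of Abca15 (3.58), Slfn8 (-1.81), Bdnf (0.89), the oxidative phosphorylation list (median -0.37) and the Y-linked list (-0.69) ended. The Egr1 call ended too, with its sign turned to 0.25, or 0.29 with the block as well. The Y-linked call also ended with GC correction (-0.68) and with a pseudocount of 5 (-1.17). Scaling to the same total gave a split of 1208 higher and 8607 lower with a median over all genes of -0.78, and upper quartile scaling gave 2482 and 4637 with a median of -0.25.

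Reactivated against Late compares the titles read as the later collection with and without the second meeting with the cue. Of 44 ribosomal protein genes, 24 rose in Reactivated (26 adjusted over the list alone), with a median of 0.64 (adjusted p = 2.43e-07, and adjusted p = 0.425 with an estimated correlation). Rplp1 rose 2.63-fold (log2 fold change 1.39 ± 0.22, adjusted p = 0.000401), Rpl38 2.46-fold, Rpl28 2.30-fold and Rps2 1.82-fold. Of 31 oxidative phosphorylation genes, 14 rose and 1 fell (18 and 1 adjusted over the list alone), with a median of 0.84 (adjusted p = 1.44e-05, and adjusted p = 0.233 with an estimated correlation). Ndufa4 rose 3.73-fold, Ndufa2 2.85-fold, Cycs 2.02-fold and Atp5b 1.94-fold. Of 12 heat shock genes, 5 rose (6 adjusted over the list alone), among them Hspa1b 6.00-fold, Bag3, a co-chaperone, 4.53-fold, Hspa8 2.10-fold and Hsp90aa1 1.57-fold (median 0.58, adjusted p = 0.00156, and adjusted p = 0.306 with an estimated correlation). Of 9 neurogenesis genes, 5 fell (8 adjusted over the list alone), among them Eomes 6.67-fold, Draxin 2.60-fold and Sox11 2.05-fold (median -1.04, adjusted p = 0.00301, and adjusted p = 0.377 with an estimated correlation).

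Markers of oligodendrocyte precursors, astrocytes and the choroid plexus were higher in Reactivated than in Late, where their sums were the lowest of all groups. In Basal, Early, Late and Reactivated the mean summed normalized counts were 503, 444, 232 and 517 for precursors. They were 6385, 5102, 2874 and 5968 for astrocytes and 1956, 2564, 818 and 2420 for the choroid list. Reactivated thus lay near Basal and Early. Of 9 oligodendrocyte precursor genes, 5 rose (7 adjusted over the list alone), among them Gpr17 8.46-fold, Pdgfra 6.88-fold and Olig2 6.19-fold (median 1.49, adjusted p = 0.00301, and adjusted p = 0.233 with an estimated correlation). The precursor gene Neu4 held 26 counts in Reactivated and 0 in Late. Of 13 astrocyte genes, 8 rose (9 adjusted over the list alone), among them Acsbg1 4.22-fold, Gfap 3.04-fold and Slc1a2, a glutamate transporter, 2.26-fold (median 1.11, adjusted p = 0.00156, and adjusted p = 0.636 with an estimated correlation). Without Reactivated 1 the astrocyte median was 0.58 and the call ended, and the precursor median was 1.19 with its call kept. Reactivated 1 had the highest sums of its group for the precursor (695, 430 and 426 in Reactivated 1, 2 and 3), astrocyte (8979, 4058 and 4868), oligodendrocyte (8556, 4019 and 3538), microglia (2196, 1174 and 893) and blood vessel lists (391, 148 and 196), but not for the choroid list (2579, 1782 and 2900). Of 9 choroid plexus and ependyma genes, 6 rose and 1 fell (6 and 1 adjusted over the list alone), Ttr, transthyretin, 6.49-fold and Enpp2 5.16-fold up and Kl 2.37-fold down (median 1.08, adjusted p = 0.0442, and adjusted p = 0.425 with an estimated correlation). That call ended without Basal 3 (1.08), Late 2 (0.97), Late 3 (1.07), Reactivated 1 (1.22) or Reactivated 3 (1.02), with the block (1.10), in limma with pseudocounts of 1 (1.14), 0.5 (1.15) or 5 (1.03), with the stricter filter (1.10), with upper quartile scaling (1.20) and with the same total. Itgam and Cx3cr1 fell 6.57-fold and 6.13-fold.

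Egr1 rose 2.22-fold in Reactivated against Late (log2 fold change 1.15 ± 0.19, adjusted p = 0.000455), and Bdnf fell 1.97-fold (-0.98 ± 0.25, adjusted p = 0.0119). Arc (0.16 ± 0.22), Fos (0.58 ± 0.45), Npas4 (0.06 ± 0.18) and Nr4a1 (0.25 ± 0.18) did not pass, though Nr4a1 passed with libraries scaled to the same total (0.61). The Bdnf call ended without Late 2 (-0.82) or Reactivated 3 (-0.77), with the same total (-0.59) and on the values as deposited (-0.86). Lrrc17 was at 964 ± 316 normalized counts in Reactivated and 2.91 ± 3.20 in Late, a rise of 347-fold that rests on 7 counts in Late (log2 fold change 8.44, or 9.68 without Late 2). Gsta3 rose 28.1-fold, Bc1, a small noncoding RNA of dendrites, 27.6-fold, Trpv4, a cation channel with 6 counts in Late, 24.3-fold and Plxnb3, a semaphorin receptor, 13.3-fold. Hist1h2af rose 12.1-fold (3.59, or 2.15 without Reactivated 2) and Ppm1h by a log2 fold change of 3.45 (2.23 without Reactivated 2). Tuba1b, a tubulin, rose 11.5-fold, F5, a clotting factor, 9.47-fold (3.24, or 3.94 without Late 3) and Rnu11 9.35-fold (3.23, or 2.51 without Reactivated 1). Hist1h2af and Tuba1b have near-identical copies, so their reads are uncertain.

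Among genes that met the naming rule, unnamed models and snoRNA, scaRNA or microRNA symbols aside, several that stood high in Late had the largest falls in Reactivated against Late, with Cdx2 down 68.4-fold, Mmrn2 44.9-fold, Nrp 38.2-fold and Dlx3 27.6-fold. Edn1, endothelin, fell 34.9-fold (log2 fold change -5.13, or -6.46 without Reactivated 3), Mybl1 26.9-fold and AF357359 21.1-fold. Suclg2 fell 22.1-fold (-4.47, or -5.22 without Reactivated 1) and Ctcfl 19.9-fold (-4.32, or -5.07 without Reactivated 1). Abca15 was at 1.84 ± 3.18 normalized counts in Reactivated (4 counts in its 3 libraries) and 55.1 ± 17.9 in Late, with a log2 fold change of -8.85 without Reactivated 1, and Cdx2 and Dlx3 held 9 and 7 counts in Reactivated.

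In all, 1615 genes rose and 1926 fell in Reactivated against Late (3541 of 15668), 792 and 1186 at least 2-fold, with no overlap for 39.7% of all genes, where chance gives 10%. With the replicate number as a block 3467 genes passed. The count was 2157 without Late 1 and 2208 without Late 2, and the calls of Bdnf (-0.84) and of the choroid plexus list (median 1.06) ended with the Rn45s share as a covariate. With libraries scaled to the same total the split was 3890 higher and 1091 lower with a median over all genes of 0.38, and upper quartile scaling gave 2260 and 1590 with a median of 0.15.

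Reactivated against Early compares the titles of the second meeting with the cue and of the first hours after conditioning. Of 21 immediate early genes, 7 rose in Reactivated (9 adjusted over the list alone), with a median of 0.57 (adjusted p = 0.00269, and adjusted p = 0.394 with an estimated correlation). Egr4 rose 2.75-fold (adjusted p = 0.00348), Ier5 2.38-fold, Fosl2 2.31-fold and Jun 1.91-fold. Egr1 rose 1.49-fold (0.57 ± 0.18, adjusted p = 0.0322). Arc (0.61 ± 0.22, adjusted p = 0.0553), Fos (0.83 ± 0.45), Npas4 (0.20 ± 0.18), Nr4a1 (0.30 ± 0.18) and Bdnf (0.28 ± 0.25) did not pass. The Egr1 call ended without Early 2 (0.57), Early 3 (0.43), Reactivated 2 (0.44), Reactivated 3 (0.59) or Basal 3 and Early 3 together (0.44), with upper quartile scaling (0.47), the same total (0.17), quantile normalization (0.50) or a fit of the 2 groups alone (0.57), on the values as deposited (0.29), and with the Rn45s covariate and the block (1.15). With GC correction below, it was lost in 13 of 31 settings. Arc passed without Basal 2 (0.61), Basal 3 (0.61), Early 1 (0.81) or Reactivated 1 (0.77), without a filter (0.60), with array weights (0.85) and in DESeq2 (0.60), and Nr4a1 passed with array weights (0.42). Of 21 presynaptic genes, 10 rose (12 adjusted over the list alone), with a median of 0.49 (adjusted p = 0.000147, and adjusted p = 0.394 with an estimated correlation). Cplx1 rose 2.60-fold, Cplx2 2.23-fold and Nrxn2 2.01-fold.

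Of 44 ribosomal protein genes, 22 rose and 1 fell in Reactivated against Early (24 and 1 adjusted over the list alone), with a median of 0.67 (adjusted p = 2.07e-08, and adjusted p = 0.394 with an estimated correlation). Rps15 rose 2.95-fold, Rplp1 2.84-fold, Rps24 2.10-fold and Rpl4 1.82-fold. Of 10 CA1 markers, 5 rose (5 adjusted over the list alone), among them Pou3f1 2.57-fold, Fibcd1 1.99-fold and Gpr161 1.52-fold (median 0.66, adjusted p = 0.0271, and adjusted p = 0.394 with an estimated correlation). The CA1 call ended without Early 3 (0.46), Reactivated 2 (0.50), Reactivated 3 (0.66) or Basal 3 and Early 3 together (0.46), and in limma with pseudocounts of 1 (0.65), 0.5 (0.65) or 5 (0.64). Of 7 genes tested in the structural noncoding RNA list, 5 rose (5 adjusted over the list alone), among them Rnu11 4.81-fold, Rpph1 4.05-fold and Rmrp 3.57-fold (median 1.84, or 2.43 without Early 3, adjusted p = 0.00269, and adjusted p = 0.394 with an estimated correlation). Of 4 Y-linked genes, 3 fell (4 adjusted over the list alone), Kdm5d 2.07-fold, Uty 2.04-fold and Eif2s3y 1.93-fold (median -0.99, adjusted p = 0.00180, and adjusted p = 0.169 with an estimated correlation).

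Flt1, a receptor of endothelial cells, rose 12.4-fold in Reactivated against Early (53.6 ± 52.3 against 3.91 ± 2.53 normalized counts, log2 fold change 3.63 ± 1.16, adjusted p = 0.0335). Its call ended without Early 1 (3.26), Early 2 (3.79), Early 3 (3.95) or Reactivated 1 (2.51), the library where the blood vessel list stood highest in its group (391, against 148 and 196). Tmem38b rose 11.2-fold, Lars2 8.39-fold (3.07, or 4.21 without Early 3), Adamts7 8.28-fold (3.05, or 3.75 without Early 3) and AF357399 8.09-fold (3.02, or 2.21 without Reactivated 1). Tmem45b fell 14.6-fold (-3.87, or -3.22 without Reactivated 2 and -4.92 without Reactivated 3) and Cenpp 8.20-fold (-3.03, or -3.82 without Reactivated 3). Klhl10 fell 7.45-fold (-2.90, or -4.19 without Reactivated 3), Slamf8 6.75-fold (-2.76, or -3.49) and Zfp758 6.56-fold (-2.71, or -4.06), each without the same library.

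In all, 2120 genes rose and 1988 fell in Reactivated against Early (4108 of 15668), 859 and 923 at least 2-fold, with no overlap for 39.1% of all genes, where chance gives 10%. With the Rn45s share as a covariate 113 genes passed and the calls of all 10 genes named for the size of their change ended, with Flt1 at 5.51, Tmem38b at 2.24, Lars2 at 1.4649, Adamts7 at 0.99, AF357399 at 1.69, Tmem45b at -2.81, Cenpp at -2.19, Klhl10 at -2.34, Slamf8 at -1.60 and Zfp758 at -1.40, as did that of the structural RNA list (median 0.38). GC correction ended the calls of the immediate early list (median 0.36), the CA1 list (0.59), the Y-linked list (-0.42) and Egr1 (0.23, or 0.25 with the block as well). The count was 1793 without Early 1 and 1698 without Early 2, and 2614 in a fit of these 2 groups alone. Scaling to the same total gave a split of 719 higher and 4285 lower with a median over all genes of -0.37, and upper quartile scaling gave 1659 and 2502.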

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

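The tests of the values as deposited, with the Rn45s share as a covariate, with GC correction, without Basal 3 and Early 3 together, without structural RNA genes, with composition taken without Rn45s and with 2 choices combined were chosen after the data were seen, and the other 16 alternatives and 12 leave-one-out fits before. Of 387 values for the 16 counts of genes and lists, 345 stayed within 1.5 times the count reported and 42 moved. Of 1368 values for the 49 called lists, 1225 kept direction and call, 142 lost the call and 1 reversed. Of 4195 values for named genes, 4043 kept both, 135 lost the call, 14 gained one and 3 reversed. Of 237 values for library composition 227 kept their direction and, in fits without 1 library, also stayed within 1 SD.

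With the Rn45s share as a covariate the counts of genes were 1468 for Early against Basal, 821 for Late against Basal, 776 for Reactivated against Basal, 533 for Late against Early, 113 for Reactivated against Early and 4366 for any difference. With the replicate block as well they were 1549, 582, 560, 382, 34 and 4191. The share runs with the groups, and the median SE for Late against Basal grew 2.06 times. On the values as deposited, which are not scaled for depth, the counts were 410 for Early, 4747 for Late and 2706 for Reactivated against Basal, 1708 for Reactivated against Late and 1815 for Reactivated against Early. Array weights gave 2759 for Early against Basal and 10291 for Late against Early, and a fit of the 2 groups alone gave 2614 for Reactivated against Early. The cause was not tested for the last 3. Leaving out 1 library gave 487 to 1224 genes for Early against Basal (lowest without Basal 2, highest without Reactivated 1). It gave 2157 to 3827 for Reactivated against Late (without Late 1 and without Basal 3) and 1698 to 4599 for Reactivated against Early (without Early 2 and without Early 3). Ranges for the others were 6129 to 8318 for Late against Basal, 4198 to 6622 for Reactivated against Basal, 4786 to 7249 for Late against Early and 7639 to 9681 for any difference. A group left with 2 libraries was assumed to vary like the others.

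With an estimated correlation 2 lists passed for Early against Basal, 1 for Reactivated against Basal and 0 for Late against Basal, Late against Early, Reactivated against Late and Reactivated against Early, where camera at the preset correlation called 14, 11, 7, 4, 7 and 6. The test with fry did not call the interneuron, chromatin and vascular lists in Early against Basal or the astrocyte list in Reactivated against Late. Fry, which asks whether a list changed at all and not whether it changed more than other genes, gave 15 for Late and 17 for Reactivated against Basal, 13 for Late against Early and 10 for Reactivated against Early. For Late against Early a pseudocount of 5 gave 2 lists and leaving out Basal 3 and Early 3 together gave 9. For Reactivated against Early the Rn45s covariate gave 14 and, with the block, 13. The cause was not tested for these 4.

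The interneuron list in Early against Basal reversed to a median of 0.03 (0.0278) without Basal 3 and Early 3 together. Egr1 in Late against Basal reversed to -0.26 (-0.2558) with libraries scaled to the same total, a setting that shifts all genes by a median of -0.87. Egr1 in Late against Early reversed to 0.25 (0.2466) with the Rn45s covariate and to 0.29 (0.2857) with the block as well. The cause was not tested for the list or for these last 2.

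As the mean of log2 values, which gives each gene of a list the same weight, the difference was -0.719 for oligodendrocyte and -0.285 for microglia markers in Late against Basal and 0.239 for astrocyte markers in Reactivated against Basal. The difference in the Rn45s share of Early against Basal, in percent of all counts, ran from -1.06 without Early 3 to 3.56 without Basal 3 and was -0.174 without Basal 1. Between Reactivated and Basal the oligodendrocyte difference ran from -0.00575 without Reactivated 1 to 0.0165, the microglia difference from -0.000825 without Reactivated 1 to 0.00496, and the Xist difference from -0.000633 without Reactivated 1 to 0.00230. Between Early and Basal the Xist difference ran from -6.13e-05 to 0.000376. At the library sizes of the data and the spread fitted to all 12 libraries, simulated 2-fold changes in Early against Basal were recovered for 49 of 100 genes. Depth was not varied, so its part in this was not tested.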

Other observations

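The tests of the Rn45s share, of GC content, of background reads and of a shared source in the Late libraries, of the CA1 list against the interneuron list and of granule cell markers were chosen after the results were seen, and what the counts of other splits would show was also written down only then. The correlation used for the Rn45s share was first computed over the genes that lost their call, where it was 0.568, and was then changed to all genes tested because the fit that defines the lost genes uses Early 3 itself. The granule cell test in Late and Reactivated was first the count of markers still called with the share in the model, 5 and 6 of 14, and was then changed to the list median.

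Lists that passed in none of the 6 comparisons gave these median log2 fold changes in Early, Late and Reactivated against Basal. Of 23 postsynaptic genes the medians were 0.11, 0.15 and 0.07 (adjusted p = 0.259, 0.399 and 0.547), of 24 translation factors 0.02, 0.17 and 0.35 (0.915, 0.809 and 0.140) and of 28 splicing and RNA-binding genes -0.01, 0.25 and 0.13 (0.960, 0.809 and 0.759). Of 15 glucocorticoid response genes they were -0.03, -0.03 and 0.03 (0.915, 0.796 and 0.804), of 18 clock genes 0.06, 0.18 and 0.36 (0.915, 0.484 and 0.166), of 12 oligodendrocyte genes -0.18, -1.02 and 0.80 (0.367, 0.456 and 0.428) and of 9 microglia genes -0.16, -1.19 and 0.27 (0.557, 0.732 and 0.636). With libraries scaled to the same total the postsynaptic, translation, splicing and clock medians were negative in Late (-0.69, -0.67, -0.57 and -0.69), where that scaling shifts all genes by -0.87. The haemoglobin genes of the blood list did not pass the filter, so the sum of that list rests on Alas2 and does not measure blood. It was 204 ± 10.7 normalized counts in Basal, 221 ± 31.8 in Early, 107 ± 8.35 in Late and 120 ± 24.1 in Reactivated. Xist was at 127, 147, 86.1 and 317 ± 349, with 720 in Reactivated 1. Mitochondrial genes were not listed under the symbols looked up.

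Each pair of groups has 10 splits of its 6 libraries, too few for a share under 0.05, and in each pair 1 split, the real one, gave as many genes. The real counts were 944 for Early, 7687 for Late and 6169 for Reactivated against Basal, 6628 for Late against Early, 3541 for Reactivated against Late and 4108 for Reactivated against Early. The highest of the other splits was 0 in edgeR each time, with up to 2058, 1359, 2267, 1644, 1669 and 2188 genes at an unadjusted p under 0.05. For any difference among the 4 groups 1 of 100 splits, the real one, gave as many genes (9180, highest other 2047), so chance can be excluded for that count.

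Granule cell markers were lower and CA1 markers higher than in Basal in Early, Late and Reactivated at the preset correlation, with granule adjusted p = 0.0185, 0.389 and 0.0874 with an estimated correlation and CA1 adjusted p = 0.00335, 0.0803 and 0.0164 with an estimated correlation. A lower share of granule cell nuclei with no other change would raise CA1 and interneuron markers alike, but in Early the CA1 median exceeded the interneuron median by 1.54 (1.16 to 1.79 in fits without 1 library), and the mean log2 of the CA1 list less that of the interneuron list was -1.49 to -1.36 in the Basal and -0.13 to 0.53 in the Early libraries, which argues against it; a permutation over genes (p = 0.0205) is descriptive. A library property that tracks the Rn45s share is argued against in Early, whose share (8.51% ± 3.83) overlapped that of Basal (7.36% ± 4.19). The granule sums did not overlap, with a lowest Basal library at 9980 and a highest Early library at 3108. With shares so alike the model with the share could hardly move the change. In it 13 of 14 granule markers stayed lower (median -2.04, SE 0.31, before and -2.09, SE 0.31, after). In Late and Reactivated such a property is argued against as the whole cause, since the list stayed called at the preset correlation (adjusted p = 8.89e-07 and 2.00e-11). The medians were -2.13 (SE 0.71, from -2.82, SE 0.32) and -2.11 (SE 0.56, from -2.46, SE 0.33), while 5 and 6 of 14 single calls were left as the error grew. A part played by such a property stays open because the share runs with these groups. Another makeup of subfields in the sorted nuclei and altered transcription within granule cells cannot be told apart, since 0 granule markers were called higher by edgeR in any of the 3 comparisons, which both allow.

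Late differed from Basal in 7687 genes, and its Rn45s share was higher in all 3 libraries. With the share in the model 669 of these genes stayed called in the same direction, among 821 called where 41.1 false calls are allowed, so that property is argued against as the whole cause for them. Of the other 7018 genes, 10 were called in the opposite direction and the rest lost their call. The median absolute log2 fold change of the 7018 went from 1.07 (SE 0.23) to 0.53 (SE 0.43), a smaller change with a larger error. Part of the smaller change follows from how these genes were picked, by the fit with the share. A library property that tracks the share is a candidate explanation for these, since the Late against Basal changes correlated across genes with Early 3 minus Early 1 and 2 (r = 0.371), and Late against Early changes with Basal 3 minus Basal 1 and 2 (r = 0.334). A trend with GC content is argued against as the whole cause, since 6114 stayed called with it removed, and a biological difference of the later collection stays open and untested.

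In Late 81 genes stood at least 8-fold above each other group, Mmrn2, Nrp, Suclg2 and Srd5a3 among them, while 42 stood at least 8-fold below. Of the 81, 23 carry Gm or Rik model names or snoRNA or microRNA symbols, with Scarna2 and AI182371 not counted. As a test of an even background such as genomic DNA, the 1122 olfactory receptor genes summed to 0.400 of Basal in Late. The mean of their log2 values, which gives each gene the same weight, was 0.187, 0.208 and 0.207 in Basal 1, 2 and 3. In Late 1, 2 and 3 it was 0.167, 0.255 and 0.184, so the groups overlap on that measure. The sum does not weigh these genes alike, so by itself it cannot decide on an even background. On the log2 scale of values plus 1, a mean of at most 0.255 in Late lies below 1 normalized count per gene. The 81 genes in Late ran from 9.34 (Gys2, Late 3) to 12216 (Mmrn2, Late 1). These values argue against an even background as the whole cause for the 81 genes. For a property that tracks the Rn45s share the values point both ways. The 81 genes were only 0.15 (0.145) higher on the log2 scale in Early 3 than in Early 1 and 2. The bootstrap interval was 0.102 to each side and is over genes, with 1 library of high share. Their median in Late against Basal was 4.23 (SE 0.41) before and 3.52 (SE 0.89) after the share entered the model. In that model 47 were still called. Late 3 had the lowest share of Late, 27.9% against 35.7% and 36.5%. There the median log2 ratio of the 81 genes to Late 1 and 2 was -0.587, against -0.0252 in other genes. By their definition the 81 genes were also at least 8-fold lower in Reactivated than in Late. The Reactivated libraries had shares of 18.8% to 27.7%, and Reactivated 1, at 27.7%, lay near Late 3. Early 3 and Reactivated argue against such a property as the whole cause. The median in Late 3 goes with it, so a part played by it stays open. One source present at a different share in each Late library would lower the 81 genes together in 1 library. Of them 77.8% were lower in Late 3, against 53.7% of 10606 other genes. Those with Snora or Snord symbols were all higher there instead. Snora65 was at 5199 in Late 3 against 3187 and 3025 in Late 1 and 2, and Snord33 at 4687 against 2809 and 2548. The set thus did not move together in Late 3, and the 3 libraries are too few to decide. Such a source cannot be told apart from a change within the cells or from a property that tracks the Rn45s share. No label names such a source, and no biological explanation was tested for these genes.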
